A study of Homo sapiens with 8 samples.

How the data were processed

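The libraries came from HEK293T cells, wild type or METTL3 knockout, that expressed FLAG-HA-tagged RBM45 from a lentivirus and were irradiated with 300 mJ/cm2 of ultraviolet light at 254 nm, per the labels' protocols. CLIP libraries followed an iCLIP protocol, and size-matched input libraries were made in parallel. The labels give 8 samples in 4 groups with 2 replicates each, and each input is called paired to its CLIP library.

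The submitters' processing notes name the hg19 build, Novoalign 3.09.00, MACS2 2.1.1.20160309, bedtools 2.25.0, HOMER 4.11.1 and deepTools 3.2.1, without a role or an order. The peak names in the deposited lists carry the caller's name, the library and a p threshold of 0.005, so peaks were called per library. Whether the input library was the caller's control is not given in the sources used here. The deposited peak lists give start and end positions, a score that equals 10 times the −log10 p cut to a whole number, a fold enrichment (a ratio over the caller's background) and the unadjusted −log10 p of each peak. These are the authors' values for single peaks, and they were used to describe, rank or filter peaks within a list and to set the values of paired peaks side by side. Fold and −log10 p were not compared between lists as a measure of changed binding. The p threshold was not adjusted for the number of positions tested, so weak peaks are kept in each list and enter every share of overlapping peaks. A list kept under the record of the first WT input holds pairs of overlapping peaks from the 2 WT CLIP lists and was used as such.

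The authors' count table was made with featureCounts 1.6.3 over the shared WT peaks with reads counted by strand (option s set to 1) and a minimum overlap fraction of 0.01, per the file headers. Its 8 count columns, and the same columns of the counting summary, carry names that match no sample label. They were not used in any step. For that reason the planned count tests were not run: CLIP against input in either genotype, the knockout against wild type, the levels of METTL3 and RBM45, the gene lists and the depth per library. Only the positions in the count table were read. All 13758 of its regions matched the deposited pairs, and each was counted 1 base longer than its peak.

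Each list repeats rows, 467329 rows for 207069 peaks in replicate 1 and 148958 rows for 64517 peaks in replicate 2, and repeats were collapsed to 1 entry per peak and strand, giving 210878 and 65587 entries. No peaks overlapped or touched within a list. Overlap meant at least 1 shared base on the same strand. The chance level came from 100 seeded shifts of replicate 2 peaks by 1 random distance per chromosome, wrapped at the chromosome's last peak. A local chance level, 100 moves of each peak by 300 to 2000 bases, was added after the files were seen, because peaks lie densely in some regions. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only and treat peaks as independent. Each chromosome except Y was compared with the rest by Fisher's exact test with Benjamini-Hochberg adjustment over 23 chromosomes, and again stratified by 10 classes of −log10 p (Mantel-Haenszel test). The chromosome tests, the strength classes, the 100-kb windows on a fixed grid and the neighbour count within 1 kb were also chosen after the files were seen.

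The rule for named peaks, fixed before the data were examined, took the 10 strongest of each list by the caller's score, and unnamed features were to be given by position. Pairs ranked by the lower of their fold enrichments, the widest peaks and the densest windows were named by rules set afterwards. Gene names, exons, introns, untranslated regions and sequence motifs were not analysed here, since they need a genome and annotation in the hg19 build.

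The overlap count was tested on simulated lists with the size of replicate 2, 65587 peaks. Planted copies of replicate 1 peaks were found in full, which checks the counting only, since such copies overlap by construction. In a list made of copies moved by up to 100 bases and peaks at random places, where the number was not fixed in advance, 13670 peaks overlapped by the count used here and 13670 by bedtools, and both gave 18914 for the real lists. Peaks at random places gave 0.98 to 1.09 times the overlap of their shifted positions. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1, the last only in these checks. The alternatives were an overlap of at least 50% of both peaks, the stronger 50% of each list, the longer list reduced to the length of the shorter, strand ignored and touching peaks merged. An overlap of at least 50% of the replicate 1 peak, lists without their 100 strongest peaks and other rankings were added later.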

Results

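The study asked where the RNA-binding protein RBM45 sits on RNA, and whether that binding depends on METTL3, the catalytic subunit of the methyltransferase complex that deposits most m6A on messenger RNA. The cells were HEK293T, an established line of transformed human embryonic kidney cells that is easily transduced, carrying a lentiviral FLAG-HA-tagged human RBM45. RNA and protein were cross-linked with ultraviolet light and the tagged protein was pulled down with its bound RNA fragments (CLIP, cross-linking and immunoprecipitation). A size-matched input, taken in parallel without the antibody step, gives the background of RNA fragments of the same length. The 8 libraries form 4 groups of 2 replicates, namely input and CLIP from wild-type (WT) cells and input and CLIP from METTL3 knockout cells. The results below come from the peak lists of the 2 WT CLIP replicates and from a list of peak pairs shared by them. Read counts per library were not used here, so the depth behind each list is unknown, and the knockout and input libraries were not analysed here. All positions are in hg19, with the first base of a chromosome counted as 1. The labels do not say whether the replicates came from separate cultures, so their differences may be technical.

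In WT cells, RBM45 CLIP peaks were narrow and numerous, and the 2 replicates differed strongly in how many were listed. The replicate 1 list held 207069 distinct peaks covering 8.47 Mb, and the replicate 2 list held 64517 peaks covering 2.44 Mb, 3.21 times fewer peaks. The median peak width was 30 bases in replicate 1 and 31 bases in replicate 2. The shortest peaks in either list were 30 bases wide, and 51.6% of replicate 1 peaks and 47.9% of replicate 2 peaks had exactly that width. The widest peak was 783 bases in replicate 1, on the minus strand of chromosome X, and 414 bases in replicate 2, at chromosome 17, 7416617 to 7417030, on the plus strand. A 698-base replicate 1 peak at chromosome 19, 54969793 to 54970490, plus strand, overlapped one of the 5 widest replicate 2 peaks, 279 bases from 54969806 to 54970084. Fold enrichment over the caller's background, as the authors' lists give it, had a median of 3.12 in replicate 1 (interquartile range 2.76 to 3.94) and 3.81 in replicate 2 (3.17 to 4.60). Peaks above 5-fold numbered 18960 in replicate 1 (9.16%) and 11633 in replicate 2 (18.03%). Above 10-fold there were 574 and 300 peaks. The plus strand carried 52.2% of the stranded entries of replicate 1 and 52.1% of those of replicate 2, where a peak listed on both strands counts once for each. Such peaks on both strands made up 1.84% of replicate 1 and 1.66% of replicate 2. With 1 list per library, the difference in peak number has no test. Numbers in the peak names run to 278233 in replicate 1 and 76064 in replicate 2, and 25.6% and 15.2% of them are absent. The listed peaks may therefore be fewer than those called, by unequal shares.

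The comparison of the 2 lists asked how far the replicates placed CLIP peaks at the same bases. The input libraries were not analysed here and may not have been the caller's control. Shared positions can therefore include background common to both CLIP libraries, and overlap above chance does not by itself show RBM45 binding. Of the 65587 stranded entries of replicate 2, 18914 shared at least 1 base on the same strand with a replicate 1 peak, which is 28.8% (95% exact binomial interval 28.5 to 29.2). Seen from the longer list, 18721 of 210878 entries, or 8.88%, overlapped replicate 2. When all replicate 2 peaks of a chromosome were moved by 1 random distance, a mean of 236 entries overlapped (range 184 to 318 over 100 shifts), so the observed number was 80.2 times that. Such shifts also carry peaks into stretches where replicate 1 lists few. The ratio therefore reflects regions that both lists cover as well as positions that they share. This ratio depends on the setting: it was 41.1 with strand ignored, 145 to 158 in shorter lists (the longer list reduced to the length of the shorter, or the stronger 50% of each), and 151 when at least 50% of both peaks had to be shared. Moving each peak by only 300 to 2000 bases left 3539 overlaps on average (range 3441 to 3699), and the observed number was 5.34 times that, or 5.33 times with strand ignored and 10.9 times with 50% of both peaks required. Both one-sided p values were 0.0099, the smallest that 100 shifts can give. All but 4 of the 18670 pairs that overlapped by position carried the same strands in both lists. The overlap fell quickly with distance. Peaks were narrow (median width 30 and 31 bases), and a shift past their width ends an overlap. The early fall therefore reflects peak width as well as how closely the replicates agree in position. A shift of 40 bases lowered it to 15.03%, a shift of 100 bases to 8.15%, and a shift of 1 kb to 5.51%. At 100 kb it was 1.24%.

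**Figure D1:**
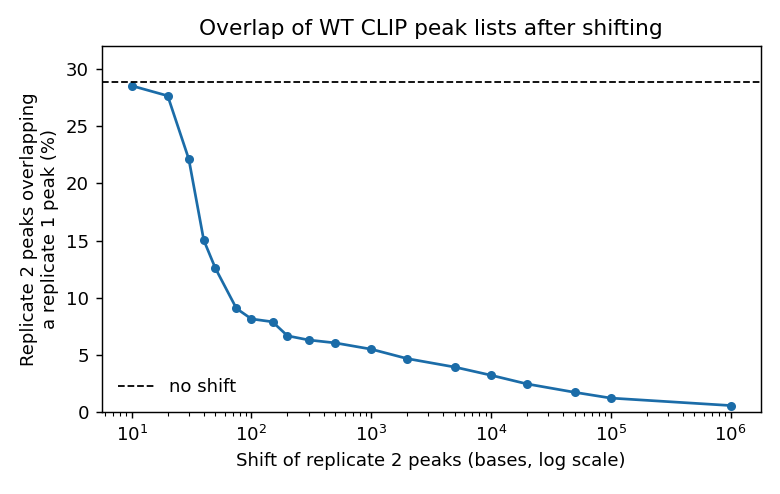
Percent of replicate 2 peaks that overlap a replicate 1 peak on the same strand (y axis) after all replicate 2 peaks are shifted by a fixed distance in bases (x axis, log scale), averaged over both directions. The dashed line marks the unshifted overlap of 28.8%, and the points fall to 0.588% at 1000 kb.

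Stronger peaks overlapped more often. In the strongest of 10 equal classes of replicate 2 peaks, ranked by the caller's −log10 p, 58.3% overlapped replicate 1 (interval 57.1 to 59.5), against 15.6% in the weakest class (14.7 to 16.5). In replicate 1 the share rose from 2.31% in the weakest class (2.11 to 2.52) to 31.3% in the strongest (30.7 to 31.9). The rise was not even from class to class. In replicate 1 the share was lowest in class 2 at 1.98% and then 6.02% in class 3, 4.52% in class 4 and 2.48% in class 5, close to the weakest class, and in replicate 2 class 2 lay lowest at 13.1%. Replicate 1 classes 1 and 2 have the same median −log10 p of 2.52, so their boundary divides tied peaks. Peaks moved by 300 to 2000 bases gave 4.26% and 8.28% in the weakest and strongest replicate 2 classes. Matched replicate 1 peaks had a median width of 40 bases and a median fold enrichment of 3.96, against 30 bases and 3.12 in unmatched ones. In replicate 2 the medians were 33 bases and 4.13 in matched peaks and 30 bases and 3.72 in unmatched ones. The rule of 1 shared base favours wider peaks, so the width differences can follow from that rule. The intervals treat peaks as independent, which neighbouring peaks of 1 library are not.

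**Figure D2:**
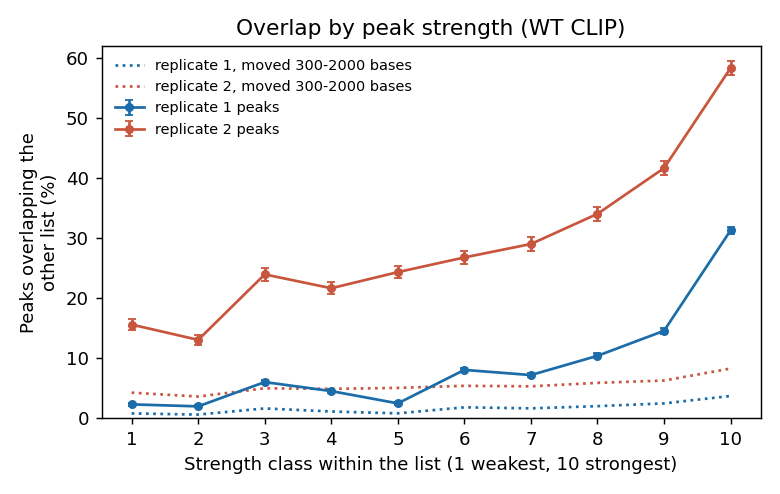
Percent of peaks that overlap the other WT CLIP list (y axis) in 10 strength classes within each list by −log10 p (x axis, class 1 weakest), with 95% exact binomial intervals as bars. Dotted lines give the overlap after each peak is moved by 300 to 2000 bases; in the strongest class 58.3% of replicate 2 and 31.3% of replicate 1 peaks overlap.

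The deposited list of shared peaks held 13758 pairs, made of 13523 replicate 1 peaks and 13492 replicate 2 peaks. These were exactly the same-strand pairs in which the overlap covered at least 50% of the replicate 1 peak. With peaks this narrow, that rule itself brings paired peaks close together. Their midpoints were a median of 4 bases apart and within 10 bases in 74.5% of pairs, with a median of 30 bases in common. The plus strand carried 7242 pairs and the minus strand 6516. The median fold enrichment of paired peaks was 4.11 in the replicate 1 list and 4.23 in the replicate 2 list. The 2 fold values of a pair lay within a factor of 2 in 90.5% of pairs (SD of the log2 ratio 0.61). The interquartile ranges of fold were narrow, 3.17 to 5.34 in replicate 1 and 3.35 to 5.35 in replicate 2. No random pairing was run for comparison. Over this narrow range of folds the Spearman correlation was 0.318 and the Pearson correlation 0.353 on the log2 scale, and the Spearman correlation of −log10 p was 0.426. These correlations are across pairs, which are not independent replicates. Both peaks exceeded 5-fold in 1919 pairs and 10-fold in 47 pairs.

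Chromosome 1 carried the most shared peaks, 10.4% of them, with 9.35% of replicate 1 and 9.97% of replicate 2 peaks. Chromosomes 16, 17, 19 and 22, pooled here because their shares were high, carried 31.6% of the shared peaks, against 20.7% of all replicate 1 peaks and 25.1% of all replicate 2 peaks. Chromosome 21 held 1.67% of shared peaks, 1.16% of replicate 1 peaks and 1.35% of replicate 2 peaks. Chromosome 19 alone held 9.52% of shared peaks (interval 9.03 to 10.03), 5.91% of replicate 1 peaks and 7.26% of replicate 2 peaks. Chromosome 18 held 0.947% of shared peaks (0.790 to 1.12), 1.93% of replicate 1 peaks and 1.57% of replicate 2 peaks. On chromosome 19, 39.8% of replicate 2 entries overlapped replicate 1 (38.4 to 41.2), the highest share, and on chromosome 18 it was 16.8% (14.6 to 19.2), the lowest. Of 23 chromosomes tested against the rest of the genome, 5 were above (16, 17, 19, 21 and 22) and 12 below at a Benjamini-Hochberg adjusted p under 0.05 (Fisher's exact test, two-sided), while 6 did not pass. The adjusted p was 1.88e-62 for chromosome 19, with an odds ratio of 1.70, and 1.28e-18 for chromosome 18, with an odds ratio of 0.494. These tests treat the entries of 1 pair of lists as independent, although 42.7% of replicate 2 entries had another within 1 kb on the strand. The p values are therefore likely too small, and neither they nor the chromosomes that passed measure variation between replicates. Moved by 300 to 2000 bases, replicate 2 entries overlapped at 9.67% on chromosome 19 and 2.54% on chromosome 18, so the ratio of observed to moved overlap ran the other way, 4.12 on chromosome 19 and 6.61 on chromosome 18.

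**Figure D3:**
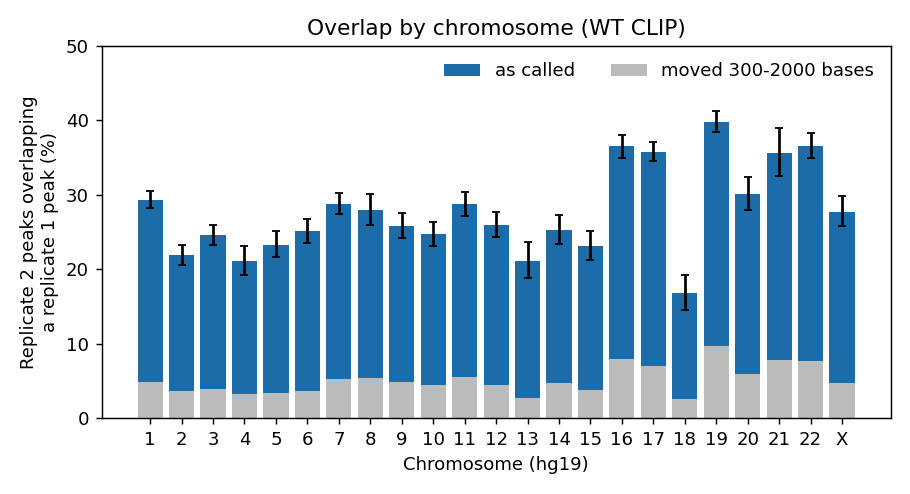
Percent of replicate 2 peaks that overlap a replicate 1 peak on the same strand (y axis) for each hg19 chromosome (x axis), with 95% exact binomial intervals as bars. Blue bars show the peaks as called and grey bars, drawn over them from the same zero line, the peaks moved by 300 to 2000 bases; chromosome 19 is highest at 39.8% and chromosome 18 lowest at 16.8%.

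Shared peaks gathered in short stretches, counted on each strand separately. Of the shared entries, 28.9% had another within 1 kb on the same strand, against 6.79% on average (range 5.98 to 7.69) in 100 random draws of as many replicate 1 entries. The draws were matched neither for strength nor for a nearby replicate 2 peak, so the excess may come from where both lists are dense. In the whole, longer lists 54.0% of replicate 1 and 42.7% of replicate 2 entries had such a neighbour, so gathering is not particular to shared peaks. In a fixed grid of 100-kb windows, 5261 windows of 1 strand held at least 1 shared peak, and 2707 of them held exactly 1. The 193 windows with at least 10 shared peaks held 20.6% of all shared peaks. The densest was chromosome 16, 89400001 to 89500000, minus strand, with 43 shared peaks among 173 replicate 1 and 105 replicate 2 entries and a median fold of 4.34 in replicate 1. The adjoining window of the same strand, 89500001 to 89600000, held 24 shared peaks. Chromosome 2, 236400001 to 236500000, plus strand, held 36 shared peaks among 152 replicate 1 and 82 replicate 2 entries. Chromosome 1, 21400001 to 21500000, minus strand, and chromosome 19, 34800001 to 34900000, plus strand, held 33 each. Chromosome 6, 20400001 to 20500000, plus strand, held 31, spread over 50.7 kb, and chromosome 17, 80000001 to 80100000, minus strand, held 29. The most compact of the windows with at least 21 shared peaks was chromosome 21, 44400001 to 44500000, minus strand, where 22 shared peaks lay within 16.4 kb. Chromosome 1, 151100001 to 151200000, plus strand, had 20 shared peaks within 20.2 kb.

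**Figure D4:**
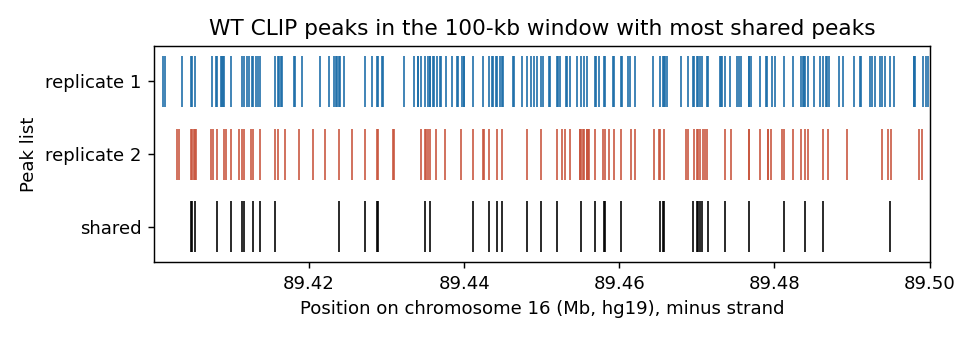
WT CLIP peaks on the minus strand of chromosome 16 from 89400001 to 89500000 (x axis, position in Mb, hg19), the 100-kb window with the most shared peaks. Each vertical line is the midpoint of 1 peak, in rows for the 173 replicate 1, 105 replicate 2 and 43 shared peaks.

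The strongest single peaks differed between the lists. All of the 10 highest-scoring replicate 2 peaks overlapped a replicate 1 peak, while 6 of the 10 highest-scoring replicate 1 peaks had no counterpart in the shorter replicate 2 list. The replicate 1 peak with the highest score lay at chromosome 7, 156995541 to 156995570, plus strand, with a fold enrichment of 33.4 and a −log10 p of 1875. Those at chromosome 6, 76525221 to 76525250, plus strand (37.1-fold), chromosome 1, 87711548 to 87711578, plus strand (38.7-fold), chromosome 8, 21770874 to 21770903, minus strand (41.2-fold), chromosome 8, 146008299 to 146008328, minus strand (34.2-fold), and chromosome 6, 34088033 to 34088062, minus strand (3.63-fold), were also unmatched. All 6 were 30 or 31 bases wide. The replicate 2 peak with the highest score, chromosome 8, 70602567 to 70602599, minus strand, had a fold of 4.17 and overlapped a replicate 1 peak of 4.46-fold that ranked 5 in its list. On the minus strand of chromosome 20, peaks at 26189783 to 26189823 (6.90-fold) and 26189293 to 26189367 (7.37-fold) were among the 10 strongest of replicate 2 and overlapped replicate 1 peaks of 8.33-fold and 10.2-fold. A high score did not require a high fold. Minus-strand peaks starting at chromosome 2, 133012560 (1.89-fold), chromosome 4, 76807204 (2.04-fold), and chromosome 8, 70602445 (2.17-fold), were also among these 10. The others ran from 3.32-fold to 57.7-fold. Binding was not separated from background at these positions. A replicate 2 peak at chromosome 6, 33258164 to 33258196, plus strand, reached 57.7-fold and its replicate 1 counterpart 42.1-fold. The replicate 2 peak at chromosome 5, 50081215 to 50081245, plus strand, had a fold of 52.1, while the replicate 1 peak it overlapped had 1.97. In the other direction, the replicate 1 peak at chromosome 3, 55908147 to 55908177, minus strand, had the highest fold of either list, 192.29, and its replicate 2 counterpart had 2.32. The pair ranked first by the lower of its 2 fold enrichments was chromosome 1, 59363663 to 59363693, plus strand, with 126 in replicate 1 and 46.8 in replicate 2. A pair at chromosome 22, 42824298 to 42824334, minus strand, had 58.5 and 25.1, and a pair at chromosome 13, 24738972 to 24739002, plus strand, had 26.5 and 26.7.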

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

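The alternatives with an overlap of at least 50% of the replicate 1 peak, the lists without their 100 strongest peaks, the ranking by fold, the stratified chromosome test and the moves by 300 to 2000 bases were chosen after seeing the data. Of the values recomputed, 12 moved and 0 reversed; the other 30 kept their side of the test's threshold, stayed within the interval of the main value or, for counts, stayed within 1.5 times it. The overlap exceeded both chance levels under every setting run, but its size did not hold: the ratio to positions moved within the chromosome, 80.2, was 41.1 with strand ignored, 145 with the longer list reduced, 158 in the stronger 50%, 151 with 50% of both peaks and 128 with 50% of the replicate 1 peak. The ratio to local moves, 5.34, was 10.9 and 9.25 under the last 2 of these and 5.33 to 6.92 otherwise. The share of replicate 2 peaks that overlapped replicate 1, 28.8%, fell to 19.6% (12842 peaks) when at least 50% of both peaks had to be shared and to 20.9% (13727 peaks) for at least 50% of the replicate 1 peak, because fewer pairs qualify. It fell to 18.6% (12225 peaks) with the replicate 1 list reduced to the length of the shorter list, and rose to 33.2% (10903 peaks) in the stronger 50% of each list. Ignoring strand gave 28.8% and leaving out the 100 strongest peaks 28.7%. In the stronger 50%, chromosome 19 held 6.41% of replicate 1, 7.598% of replicate 2 and 9.01% of shared peaks, and chromosome 18 held 1.63% of replicate 1 and 1.28% of replicate 2 peaks; the cause was not tested. The matched share of the 100 strongest replicate 2 peaks, 91.0%, was 78.0% with 50% of both peaks required. Chromosomes above the rest numbered 5 under every setting run, and those below it 12, or 13 with X when stratified by strength. Merging touching peaks changed neither peak number, and the peak midpoint gives the same chromosome. No paired analysis was possible because the count columns carry no sample labels. For that reason the alternatives on normalization, count tool, low-count filter, block, left-out libraries and gene lists were not run, nor were annotation order, motif windows and peaks per gene. Leaving out a replicate leaves 1 list and no overlap. The depth of the libraries is unknown, so the difference in list length was not corrected for it.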

Other observations

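The tests of the matched share against the next strongest peaks, of width and fold in the strongest peaks, of rows per read and of the packing on chromosomes were chosen after the results were seen. Some values belong to no comparison. Peak numbers run to 278233 in replicate 1 and 76064 in replicate 2, of which 71164 (25.6%) and 11547 (15.2%) are absent from the lists. In replicate 1 the absent numbers form 9004 runs, the longest of 542, against 52620 to 53247 runs in 100 random removals of as many numbers. In replicate 2 they form 3483 runs, against 9735 to 9882. Where replicate 1 lacks at least 5 numbers between neighbouring peaks 10 to 500 kb apart, replicate 2 has 2.11 peaks per Mb, against 15.8 per Mb where none is absent.

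Of the 100 strongest replicate 1 peaks, 56.0% overlapped replicate 2 (interval 45.7 to 65.9), while 91.0% of the 100 strongest replicate 2 peaks overlapped replicate 1, which has the longer list. One candidate explanation is stacks of copies of single fragments in replicate 1, which would be narrow and lie alone: the 44 unmatched peaks were narrower than the 56 matched ones (median 31 against 44 bases, permutation p = 2e-05, the smallest that 100000 resamples give), with a median fold of 15.2 against 7.44 (permutation p = 0.0523), and 65.9% against 48.2% had no other replicate 1 peak within 1 kb on the strand (Fisher's exact p = 0.105). It stays open, since unmatched peaks had the lower median width in both whole lists (30 against 40 bases and 30 against 33), and among the 900 next strongest they lay alone more often in replicate 1, 44.5% (39.2 to 49.9) against 24.1% (20.6 to 27.9), but also in replicate 2, 36.2% (29.5 to 43.4) against 23.4% (20.4 to 26.7), although not in the 100 strongest of replicate 2, 22.2% of 9 against 36.3% of 91. The width difference cannot decide either, because a match needs only 1 shared base and wider peaks meet that rule more easily. Too little signal in replicate 2 also stays open, since the depth of that library is unknown. The matched share of replicate 1 peaks was 56.0% in the 100 strongest and 61.3% in the 900 next (Fisher's exact p = 0.331). That of replicate 2 peaks was 91.0% and 78.2% (Fisher's exact p = 0.00165). Among the 100 strongest replicate 1 peaks, the median −log10 p was 123 in unmatched and 97.8 in matched ones (permutation p = 0.355). A general lack of signal should lose weaker peaks first. Over the whole replicate 1 list the matched share rose unevenly from 2.31% in the weakest of 10 classes to 31.3% in the strongest. That rise goes with the explanation but does not single it out. The comparisons within the strongest replicate 1 peaks did not pass 0.05 and cannot decide. No biological explanation was tested.

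The repeated rows and the strands of the lists form a second pattern. Rows do not appear to count reads: the row number was equal in both lists for 13757 of the 13758 shared pairs, and its Spearman correlation with fold, across peaks, which are not independent, was 0.0262 in replicate 1 and 0.0113 in replicate 2. Rows written once per annotated interval at a position, which would also give the strand, remain a candidate explanation, since 99.979% of 18670 pairs overlapping without regard to strand carried the same strands in both lists, all but 4. If so, the strand of a peak may be that of an annotated transcript and not that of its reads, and same-strand overlap carries little beyond overlap by position. The share of overlapping replicate 2 peaks was 28.8% with or without regard to strand. Ignoring strand lowered the ratio to positions moved within the chromosome from 80.2 to 41.1. Moved peaks kept their strand, so the strand rule lowered their overlap, and the higher ratio is no evidence that strand carries information. No biological explanation was tested.

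The higher matched share on chromosomes 16, 17, 19, 21 and 22 was weighed against closer packing of replicate 1 peaks there. The pooled share was 37.2% on these 5 chromosomes, with 8.07% after moves of 300 to 2000 bases, and 25.8% on the other 18, with 4.43% after them. The observed share minus the moved share was taken as a percent of the peaks that did not overlap after moving. It was 31.7% (interval 30.9 to 32.4) on the 5 chromosomes, against 22.4% (21.97 to 22.8) on the other 18. The ratio of observed to moved overlap went the other way, 4.61 on the 5 chromosomes against 5.83. The 5 chromosomes were picked for their high matched share in these same lists, and the intervals treat peaks as independent. The direction also depends on whether a difference or a ratio is taken. These values therefore cannot decide how much chance overlap from packing contributes, and packing stays open. Transcript abundance, gene density and base composition stay open, untested, and no biological explanation was tested.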
